A study of Arabidopsis thaliana with 18 samples.

How the data were processed

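RNA sequencing data of Arabidopsis thaliana whole aerial parts were analysed for 18 samples, 3 libraries for each of 6 groups. The groups were an Italian (IT) and a Swedish (SW) ecotype, each in the warm (22 °C), after 1 week at 4 °C and after 2 weeks at 4 °C. RNA was extracted with an RNeasy kit and made into standard Illumina libraries, per the labels. The submitters' processing notes name TopHat 1.4.1, Cufflinks 2.1.1, Cuffdiff and the genome build TAIR10. Their settings, the order of the steps and the way the 3 libraries of a group were combined are not given in the sources used here.

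The deposited table gives FPKM values, and per its headers 1 value for each gene and group, made by the authors from the libraries of that group. It held 33557 genes and 6 value columns. No values per library were used here. The planned design, limma on log2 values of 18 libraries with adjusted p-values, could therefore not be used, and no test, p-value, standard deviation or camera test of lists was computed. The fallback written into the design was used instead, in which both values and their ratio are given. The depth behind the values is unknown, and the FPKM sums ranged from 823963 to 1034038 per group. The lower edge of the low values, taken as the 5th percentile of FPKM times gene length in kb among values above 0 and up to 0.2 FPKM, differed at most 1.29-fold between groups.

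Genes with an FPKM of at least 1 in at least 1 group were kept (19639 genes); the plan asked for at least 3 libraries. FPKM values were used as deposited, without further scaling, as log2(FPKM + 1). A gene was counted as higher or lower when its log2 ratio was 1 or more, or -1 or less. A gene listed at exactly 0 in a compared group was given no ratio, a choice made after abundant genes at 0 were seen. The comparisons were cold against warm in each ecotype at 1 and 2 weeks, 2 weeks against 1 week in each ecotype, SW against IT in each condition, and the difference of the log2 cold responses at 1 and 2 weeks. The overlap of the cold responses of IT and SW was counted beside the number expected for independent lists. The overlap of 1 and 2 weeks within an ecotype, which would share the warm group, was not computed.

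Gene names, types and coordinates came from the TAIR10.1 annotation, matched to the table by locus (32813 loci, 97.8%; 744 unmatched). The reads were presumably aligned to the Columbia reference, so variants of either ecotype can lower a value. Close paralogs (KIN1 and KIN2, COR15A and COR15B, the RBCS, LHCB1 and LHCB2 genes, and PDF1.2a, PDF1.2b and PDF1.2c) may share reads.

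Before the data were examined, 23 gene lists with 342 loci were written by hand. They covered CBF genes, CBF regulators, cold-regulated genes, early cold transcription factors, sugar and proline, flavonoid and anthocyanin, clock, photosynthesis, flowering and vernalization, salicylic acid defence, jasmonate, glucosinolate, abscisic acid and dehydration, RNA chaperones and ribosome assembly, membrane lipids, antioxidant and photoprotection, and gibberellin and growth genes. Markers of root, flower, seed, epidermis and vein, and senescence, and 12 reference genes completed them. For each list with at least 4 measured members the median log2 ratio was placed among 10000 random lists matched on mean expression in 20 bins (seed 1). These percentiles are not p-values. Named genes were CBF1, CBF2, CBF3, COR15A, RD29A, KIN2, GOLS3 and FLC in each comparison, and the 6 largest ratios in each direction with at least 5 FPKM in the higher group (4 for the differences of responses). For each list described, up to 3 members at 2-fold or more with the largest ratios were added, with the most abundant member within 2-fold.

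The calls and list percentiles were tested on simulated data built from the IT warm values alone. A simulated IT 1 week group was made from them with noise of 0.2 on the log2 scale, drawn separately for each gene. Differences were planted only in genes of at least 5 FPKM in IT warm, so the recovery says nothing of genes below that level. Of 50 genes planted at a log2 ratio of 1.5, 50 were called, and of 50 planted at -1.5, 49. Of 18030 genes without a planted difference 0 were called, and a planted list of 20 genes lay at percentile 100. The call limit of 1 lies far outside noise of 0.2, so the 0 calls were fixed in advance and measure no rate of false calls. The noise was chosen by hand and does not measure the spread between plants.

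Counts of genes, 216 list medians, 823 gene ratios and the correlations were recomputed under 9 alternatives, with 1 choice changed at a time. A filter of 5 FPKM left 198 of the medians and 746 of the gene ratios, and protein-coding genes alone left 795 of the ratios. Percentiles of lists and overlaps expected for independent lists were not recomputed, and word-based families were recomputed under the 3 scalings alone. The 7 planned ones were pseudocounts of 0.1 and 0.25, no filter on low values, a filter of 5 FPKM, upper-quartile scaling, quantile normalization and scaling by the reference genes. The last set the median level of the reference genes equal between groups, which does not bring the median of their ratios to 0. The 2 added after the data were seen kept genes listed at 0 and used protein-coding genes only. Python 3.11.15, NumPy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used.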

Results

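Transcript levels were measured by RNA sequencing in whole aerial parts of Arabidopsis thaliana plants of an Italian (IT) and a Swedish (SW) ecotype, which are natural accessions of the species. The series concerns natural variation of the CBF cold-response pathway and its part in adaptation to local climates. Plants grew at 22 °C in a 12 h photoperiod for 18 days, and were then harvested warm or moved to 4 °C for 1 or 2 weeks. Tissue was taken 4 h after lights on (ZT4). The 18 libraries formed 6 groups of 3, with 1 group for each ecotype and condition. The light was 100 to 120 µmol m-2 s-1 during growth and about 35 µmol m-2 s-1 at 4 °C. Cold, dimmer light and greater age therefore came together in each comparison of cold with warm plants.

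The table gave 1 combined FPKM value (fragments per kilobase of transcript, scaled to the mapped fragments of the library) per gene and group for 33557 genes. Of these, 19639 reached 1 FPKM in at least 1 group and 18804 of those were protein coding. The FPKM values summed to 823963 in IT warm, 1013445 in IT after 1 week of cold, 910807 in IT after 2 weeks, 902774 in SW warm, 1004255 in SW after 1 week and 1034038 in SW after 2 weeks. The median FPKM of the kept genes lay between 10.4 and 10.9 in the 6 groups. No counts per library were analysed, so the depth behind each value is unknown. There were no replicate values, so no difference below could be held against replicate spread and no p-value is given. Differences are log2 ratios of FPKM + 1, and a gene was counted as higher or lower at 2-fold or more. The added 1 pulls ratios of values near or below 1 FPKM toward 0: with 0.1 in its place, 175 of 823 gene ratios differed by more than 0.5.

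In the TAIR10.1 annotation the 3 CBF genes lay side by side on chromosome 4, CBF2 (AT4G25470) at 13015250 to 13016235, CBF3 (AT4G25480) at 13018010 to 13019400 and CBF1 (AT4G25490) at 13021780 to 13022996. COR15A (AT2G42540) lay on chromosome 2 at 17710441 to 17712330 beside its relative COR15B (AT2G42530) at 17708593 to 17710433. KIN1 (AT5G15960) at 5209717 to 5210826 and KIN2 (AT5G15970) at 5211719 to 5212743 were neighbours on chromosome 5. The flowering repressor gene FLC (AT5G10140) lay on chromosome 5 at 3173382 to 3179448. Reads shared between such close relatives could not be traced here, so the split of a sum between COR15A and COR15B or between KIN1 and KIN2 is uncertain.

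The cold response of the Italian ecotype after 1 week was marked by high levels of CBF and cold-regulated transcripts. CBF1, CBF2 and CBF3 encode the transcription factors that switch on cold-regulated genes. CBF2 stood at 27.3 FPKM in the cold against 0.639 in the warm, CBF3 at 29.1 against 3.65, and CBF1 was low in both at 1.62 and 0.123. The chloroplast protectant gene COR15A reached 5067 FPKM against 107, and KIN1 reached 2263 against 4.29, the largest ratio among genes of at least 5 FPKM (log2 ratio 8.74). Of 24 cold-regulated genes, 12 were at least 2-fold higher, 0 were lower and 12 lay within 2-fold, with a median log2 ratio of 1.03, at percentile 99.9 of the matched random lists. The dehydrin gene LTI30 had a log2 ratio of 5.17, KIN2 of 3.10 and RD29A of 2.86, while the membrane protein gene COR413PM1 stayed within 2-fold at 0.86. GOLS3, which encodes an enzyme of raffinose synthesis, was at 19.1 FPKM against 2.3003, and FLC at 48.2 against 63.2.

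Genes of the circadian clock differed as a group at this hour of the day. Of 21 clock genes 12 were at least 2-fold higher, 0 were lower, and the median of 1.16 lay above all 10000 matched random lists. ELF4, a part of the evening complex, was at 111 FPKM against 2.43, the photoreceptor gene FKF1 at 88.5 against 3.37 and LUX at 23.9 against 1.71, while LNK2 had a log2 ratio of -0.59. RVE2, a MYB-like relative of CCA1, and COR27, a cold-induced regulator of the clock, were among the largest ratios at 5.69 and 6.75. AT4G33980 (6.03) and AT4G18422 (5.76) stood beside them. Genes of RNA chaperones and ribosome assembly were also higher, with 11 of 18 at least 2-fold higher, 0 lower and a median of 1.34, at percentile 99.99 of the matched random lists. The nucleolar gene FIB2 had a log2 ratio of 3.94, the glycine-rich RNA-binding protein gene GRP7 of 3.67 and NOP56 of 2.26, against -0.12 for GRP8. In the sugar and proline list 7 of 20 genes were at least 2-fold higher, among them the beta-amylase gene BAM3 (AT4G17090, 3.35) and the proline synthesis gene P5CS2 (1.94), 2 were at least 2-fold lower, and P5CS1 lay within 2-fold (0.58). The median of that list was 0.41, at percentile 90.9 of the matched random lists.

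Genes of photosynthesis, salicylic acid defence and growth were lower in the cold IT plants. Of 20 measured photosynthesis genes 6 were at least 2-fold lower and 1 was higher (median -0.83). Rubisco small subunit genes were among them, with RBCS3B at 717 FPKM against 4233 and RBCS2B at 642 against 1855; the light-harvesting genes LHCB4.2 and LHCB3 had log2 ratios of -1.68 and -0.86. LHCA4, LHB1B2 and RCA were listed at 0 in IT warm and so had no ratio. The salicylic acid defence list had 9 of 18 genes at least 2-fold lower and 3 at least 2-fold higher (median -1.08, below all 10000 matched random lists). The transcription factor gene WRKY70 was at 45.1 FPKM against 235, whereas the pathogenesis-related genes PR5 (7128 against 283) and PR2 (3079 against 409.9) went the other way, and SARD1 lay just within 2-fold at -0.996. In the gibberellin and growth list 4 of 15 genes were at least 2-fold lower and 0 were higher (median -0.79). The expansin genes EXPA8 (-4.47) and EXPA1 (-1.33) and the cell wall enzyme gene XTH22 (-1.43) led that list, and XTH4 was within 2-fold (0.92). Of 23 flavonoid and anthocyanin genes 7 were at least 2-fold lower and 1 was higher (median -0.42), with log2 ratios of -2.09 for DFR, -1.88 for UGT79B1, 2.56 for MYB111 and 0.48 for CHS. The largest ratios on the lower side were NUDT24 (-6.88), MEE3 (-5.46), the glutaredoxin gene AT2G47880 (-5.18), cPT4 (-4.55), EXPA8 and ATSDI1 (-4.15).

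Flowering, membrane lipid and jasmonate genes stood close to their warm levels. Within 2-fold were 10 of 11 CBF regulators, 17 of 17 flowering genes, 13 of 14 membrane lipid genes, 10 of 11 jasmonate genes and 23 of 27 glucosinolate genes. Of the antioxidant genes 8 of 11 lay within 2-fold, and of the abscisic acid genes 12 of 15. Early cold transcription factors went both ways, with 4 of 15 higher, 3 lower and 8 within 2-fold. Of all genes 17.9% were past 2-fold in this comparison. Exceptions in these lists included PIF4 (-1.85), the early light-induced gene ELIP2 (3.68), the fatty acid desaturase gene ADS2 (1.82), the zinc finger gene ZAT12 (2.06) and ADH1 (4.11). Across all genes 1941 were at least 2-fold higher and 1532 at least 2-fold lower of 19362 with a ratio. That majority turned to 1643 and 1878 under upper-quartile scaling and 1717 and 1954 under reference-gene scaling, and was 1755 and 1729 under quantile normalization.

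After 2 weeks of cold the Italian plants held high levels of the same cold markers. CBF2 was at 24.1 FPKM against 0.639 in the warm, CBF3 at 32.8 against 3.65 and CBF1 at 2.32 against 0.123. COR15A stood at 3062 FPKM, KIN1 at 698, KIN2 at 3824, RD29A at 185 and GOLS3 at 22.5, with log2 ratios to the warm of 4.83, 7.05, 3.19, 2.80 and 2.83. FLC, which cold represses over weeks in vernalization, was at 30.0 against 63.2 (-1.05). Of 24 cold-regulated genes 13 were at least 2-fold higher and 0 lower (median 1.095, above all 10000 matched random lists, and 0.65 under reference-gene scaling), and COR413PM1 was the most abundant of those within 2-fold (0.58). The clock list had 12 of 21 genes at least 2-fold higher and 0 lower (median 1.34, and 0.85 under that scaling), led by ELF4 (4.82), FKF1 (4.58) and LUX (3.26).

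Flavonoid, photosynthesis and glucosinolate genes were lower at 2 weeks. In the flavonoid list 10 of 23 genes were at least 2-fold lower and 1 was higher (median -0.81, below all 10000 matched random lists). The anthocyanin genes DFR (4.302 against 35.2 FPKM), UGT79B1 (2.09 against 15.6) and LDOX (8.85 against 47.7) were the clearest, and CHS lay within 2-fold (-0.33). Photosynthesis had 9 of 20 genes at least 2-fold lower and 0 higher (median -0.94), with RBCS3B at -3.02, RBCS2B at -2.66, LHCB4.2 at -1.76 and LHCA1 within 2-fold at -0.95. Glucosinolates are sulfur-rich defence compounds, and 9 of the 27 genes of that list were at least 2-fold lower against 3 higher (median -0.51). AOP2 was at 103 FPKM against 519 and FMOGSOX3 at 8.84 against 45.0, while MYB76 had a log2 ratio of -1.73 and the myrosinase gene TGG1 of -0.26. Growth genes had 5 of 15 at least 2-fold lower (median -0.72), with EXPA8 at -3.05, GA2OX1 at -1.28 and EXPA1 at -1.23. Scaled by reference genes, the medians were -1.21 for the flavonoid, -1.46 for the photosynthesis, -1.02 for the glucosinolate and -1.20 for the growth list.

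Pathogenesis-related and floral genes stood high in the 2-week IT plants. PR1 was at 11644 FPKM against 867, PR5 at 6916 against 283 and PR2 at 2001 against 409.9, but EDS1 was within 2-fold (-0.69) and the list as a whole was spread, with 4 of 18 genes at least 2-fold higher, 1 lower and a median of 0.22 that turned to -0.27 under reference-gene scaling. Of 5 measured flower markers 4 were at least 2-fold higher (median 1.27), all at low levels, with the floral MADS box genes SEP3 at 2.60 FPKM against 0.124, SEP2 (AT3G02310) at 1.67 against 0.0452 and AP1 at 1.48 against 0.0283. The floral inducer gene FT was at 2.78 FPKM against 0.0531 and SOC1, which promotes flowering, at 83.2 against 40.0. The senescence marker SAG12 was at 1.76 FPKM against 0.243 and SAG13 at 291 against 137. RNA chaperone and ribosome assembly genes had 6 of 18 at least 2-fold higher (median 0.68, and 0.18 under reference-gene scaling), including GRP7 (2.82), FIB2 (2.59) and NOP56 (1.06) but not NUC1 (0.58). The sugar and proline list had 6 of 20 genes higher and 2 lower at 2-fold, with a median of 0.48 that turned to -0.00212 under reference-gene scaling, and the sucrose synthase gene SUS1 had a log2 ratio of 2.302. Among the largest ratios were COR27 (6.68), the lipid-transfer protein gene EARLI1 (5.57), GRP3S (5.53), AT4G33980 (5.52) and RVE2 (5.11) on the higher side. NUDT24 (-6.87), cPT4 (-4.68), AT3G28270 (-4.67), AT3G24100 (-4.60), AT4G01390 (-4.36) and AT1G13650 (-3.88) were lower.

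In this comparison 1362 genes were at least 2-fold higher and 1247 at least 2-fold lower of 19382, a share of 52.2% higher. Scaling the groups to the median level of 12 reference genes shifted the median of all genes by -0.43 and gave 547 higher and 3145 lower, a share of 14.8%. That scaling overshot the reference genes themselves, whose own median log2 ratio went from 0.32 to -0.18. The majority also turned under upper-quartile scaling (1117 and 1482) and quantile normalization (1196 and 1465).

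The Swedish ecotype answered 1 week of cold with larger ratios of the cold-regulated genes. COR15A was at 13809.5 FPKM against 108 in the warm, RD29A at 1126 against 8.97, KIN2 at 4888 against 97.3, LTI30 at 1364 against 2.48 and GOLS3 at 205 against 2.16. KIN1 had the largest log2 ratio, 9.45. CBF2 was at 38.5 FPKM against 0.436, CBF3 at 44.9 against 1.09 and CBF1 at 2.26 against 0.0422. Of 24 cold-regulated genes 21 were at least 2-fold higher, 0 were lower and 3 lay within 2-fold, among them ERD14 (0.71). The list median was 3.22, above all 10000 matched random lists. FLC differed little, at 176 FPKM against 167, while its relative MAF3 was at 82.0 against 22.8.

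The clock, sugar, flavonoid and dehydration lists were higher in cold SW plants. Clock genes had 12 of 21 at least 2-fold higher and 0 lower (median 1.49), led by FKF1 (112 against 0.261 FPKM), ELF4 (135 against 0.633) and PRR5 (155 against 2.18), with LNK2 within 2-fold (-0.71). The sugar and proline list had 9 of 20 higher and 0 lower (median 0.79, at percentile 99.99 of the matched random lists), including BAM3 (4.07) and SUS1 (3.54), whereas P5CS1 was at 0.49. In the flavonoid list 6 of 23 genes were at least 2-fold higher and 1 was lower (median 0.64, at percentile 99.95 of the matched random lists), with the regulator MYB111 at 3.82, the flavonol synthase gene FLS1 at 2.39, CHS at 2.16 and the repressor MYBL2 at -0.97. Abscisic acid and dehydration genes had 6 of 15 higher and 0 lower (median 0.61), with ADH1 at 347 FPKM against 5.78, the dehydrin gene RAB18 (AT5G66400) at 71.5 against 11.4 and CYP707A1 at 10.9 against 0.938, but RD22 at -0.30 on the log2 scale. Early cold transcription factors had 6 of 15 higher and 1 lower (median 0.83), with MYB73 at 2.71, ZAT12 at 2.53, TEM2 at -1.88 and MYB44 at 0.72. RNA chaperone and ribosome assembly genes had 4 of 18 higher (median 0.81). Jasmonate genes had 4 of 11 higher and 0 lower, with a median of 0.43 that turned to -0.12 under reference-gene scaling; PDF1.2a was at 1.87, JAZ1 at 1.81, AOC2 at 1.23 and LOX2 at 0.73. The genes AT1G69140 (8.68), AT4G18422 (7.71) and AT1G16850 (7.65) were among the largest ratios, next to COR27 (7.23). Reference-gene scaling lowered the medians to 0.96 for the clock, 0.24 for the sugar and proline, 0.14 for the flavonoid, 0.25 for the abscisic acid, 0.30 for the early cold transcription factor and 0.27 for the RNA chaperone list.

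Photosynthesis, defence and growth genes were lower in SW after 1 week as well. Photosynthesis had 9 of 20 genes at least 2-fold lower and 0 higher (median -0.97), with RBCS3B at 364 FPKM against 5817, RBCS2B at 290.2 against 3892, the carbonic anhydrase gene CA1 at 739 against 2406 and LHCA1 at -0.95. The salicylic acid list had 8 of 18 lower and 1 higher (median -0.84, below all 10000 matched random lists), with WRKY70 at -2.81, PR5 at 2.65, NIMIN1 at -2.41 and PR1 within 2-fold at 0.79. Growth genes had 5 of 15 lower and 1 higher (median -0.88), with EXPA8 at -4.61, EXPA1 at -3.08, XTH7 at -2.77 and XTH4 at -0.16. The gibberellin-regulated gene GASA6 (-4.27), the aquaporin gene TIP2 (-3.93) and AT1G73600 (-3.69) completed the largest ratios on the lower side. The glucosinolate list had 2 of 27 lower and 2 higher, with a median of -0.42, at percentile 0.01 of the matched random lists. These medians also depended on the scaling. By reference genes they were -1.52 for photosynthesis, -1.35 for the salicylic acid, -1.22 for the growth and -0.97 for the glucosinolate list.

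In SW after 1 week 1511 genes were at least 2-fold higher and 1200 at least 2-fold lower of 19347 (55.7% higher). Reference-gene scaling shifted the median of all genes by -0.46 and gave 684 higher and 3271 lower (17.3%). Upper-quartile scaling (1287 and 1446) and quantile normalization (1268 and 1362) turned the majority as well.

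Swedish plants after 2 weeks of cold kept very high levels of cold-regulated transcripts. COR15A was at 13319 FPKM, KIN2 at 4343, RD29A at 1532, LTI30 at 1031 and GOLS3 at 354, with log2 ratios to the warm of 6.93, 5.47, 7.26, 8.21 and 6.81. CBF1 was at 4.53 FPKM, CBF2 at 39.8 and CBF3 at 51.2, against 0.0422, 0.436 and 1.09 in the warm. Of 24 cold-regulated genes 18 were at least 2-fold higher and 0 lower (median 3.17, above all 10000 matched random lists), KIN1 having the largest ratio (9.38) and ERD14 lying within 2-fold (0.78). FLC was at 105 against 167 FPKM, and VIN3, a cold-induced gene needed for its silencing, at 3.27 against 0.00458. SOC1 was at 36.3 against 4.07 and AGL19 at 13.0 against 2.40, among 4 of 16 flowering genes that were at least 2-fold higher.

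Defence genes were lower across the salicylic acid and glucosinolate lists. In the salicylic acid list 13 of 18 genes were at least 2-fold lower and 0 higher (median -1.51, below all 10000 matched random lists), with WRKY70 at 19.95 FPKM against 156, NIMIN1 at 2.303 against 19.0 and WRKY38 at 1.16 against 10.8, while PR1 was at 870.0 against 719.8. In the glucosinolate list 15 of 27 were lower and 1 was higher (median -1.05, below all 10000 matched random lists), with SOT17 at -2.01, ESM1 at 1.81, FMOGSOX3 at -1.68 and TGG1 at -0.19. Photosynthesis had 6 of 20 genes lower (median -0.62), with RBCS3B at -4.14, RBCS2B at -3.84, CA1 at -1.51 and LHCB3 at -0.85. Growth genes had 6 of 15 lower (median -0.77), with EXPA8 at -3.63, XTH7 at -2.47 and XTH22 at -2.33. Scaled by reference genes, the medians were -2.04 for the salicylic acid, -1.64 for the glucosinolate, -1.25 for the photosynthesis and -1.21 for the growth list.

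On the higher side, clock genes had 12 of 21 at least 2-fold higher (median 1.49), with FKF1 at 6.75, ELF4 at 6.13 and PRR5 at 5.45. The sugar and proline list had 9 of 20 higher and 1 lower (median 0.84, above all 10000 matched random lists), including BAM3 (4.18) and SUS1 (3.74). Reference-gene scaling lowered these medians to 0.88 and 0.31. The flavonoid list was split, with 7 of 23 higher, 4 lower and a median of 0.29 that turned to -0.20 under reference-gene scaling. MYB111 (4.03), FLS1 (2.29) and CHS (2.12) were higher there, and the late anthocyanin genes DFR (-1.14) and LDOX (-1.104), chosen after their values were seen, were lower. The next 3 lists did not stand out as wholes, and their medians turned under reference-gene scaling. The abscisic acid list had 5 of 15 genes higher and 0 lower (median 0.15, at percentile 73.6 of the matched random lists, turned to -0.35), with ADH1 at 5.59 and NCED3, which makes abscisic acid, at 2.15. The antioxidant list had 2 of 11 higher and 1 lower (median 0.06, at percentile 17.2 of the matched random lists, turned to -0.57, and to -0.04 and -0.35 under upper-quartile and quantile scaling), with the early light-induced genes ELIP2 and ELIP1 at 4.22 and 4.105. The RNA chaperone list had 4 of 18 higher and 0 lower (median 0.48, at percentile 93.6 of the matched random lists, turned to -0.13), with GRP7 at 4.52. AT1G69140 (9.24), AT1G16850 (7.83), AT4G18422 (7.75) and the kinase gene CIPK25 (7.53) had the largest ratios beside KIN1 and LTI30. The largest on the lower side were GASA6 (-4.94), the SAUR-like gene AT1G72430 (-4.22), RBCS3B, AT3G24100 (-4.08), TIP2;2 (-3.97) and TIP2 (-3.90).

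In SW after 2 weeks 1265 genes were at least 2-fold higher and 1444 at least 2-fold lower of 19328 (46.7% higher). Under reference-gene scaling, with a shift of -0.52, the split was 470 and 3828 (10.9% higher).

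**Figure D1:**
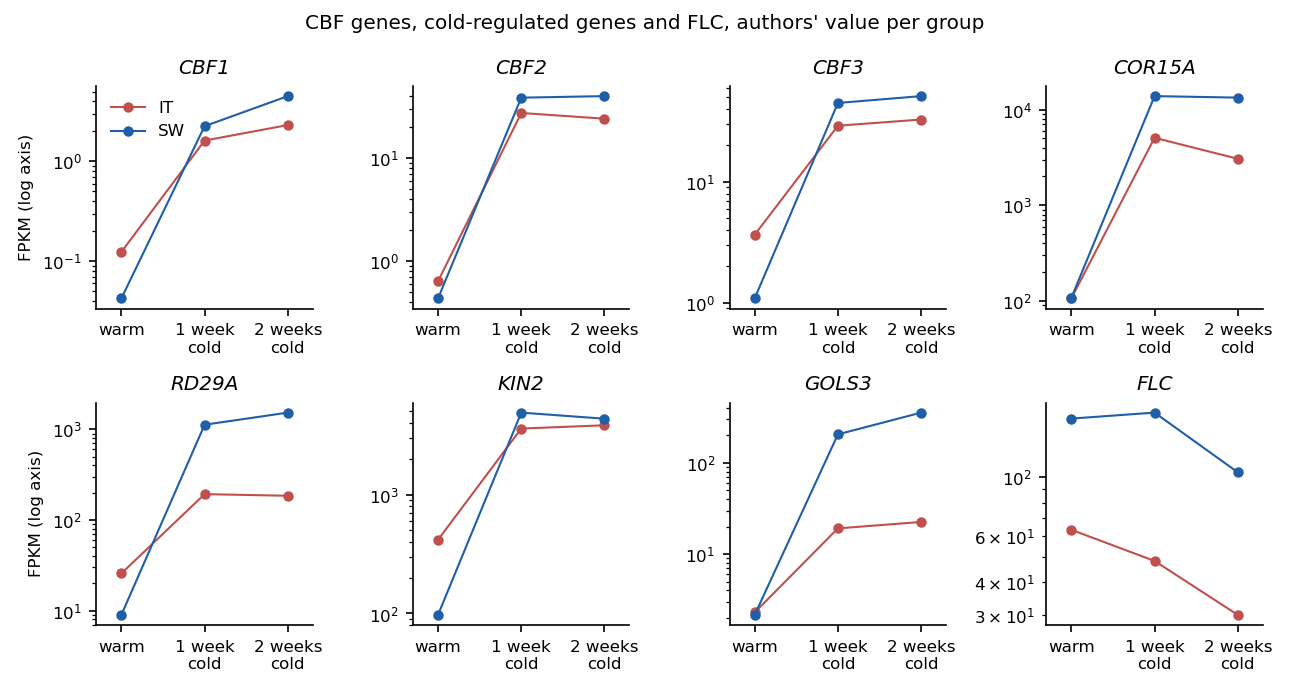
FPKM on a log axis, 1 combined value per group without error bars, of CBF1, CBF2, CBF3, COR15A, RD29A, KIN2, GOLS3 and FLC in IT (red) and SW (blue) plants in the warm and after 1 and 2 weeks at 4 °C. RD29A reached 1532 FPKM in SW and 185 in IT after 2 weeks, and FLC was higher in SW than in IT in all 3 conditions.

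**Figure D2:**
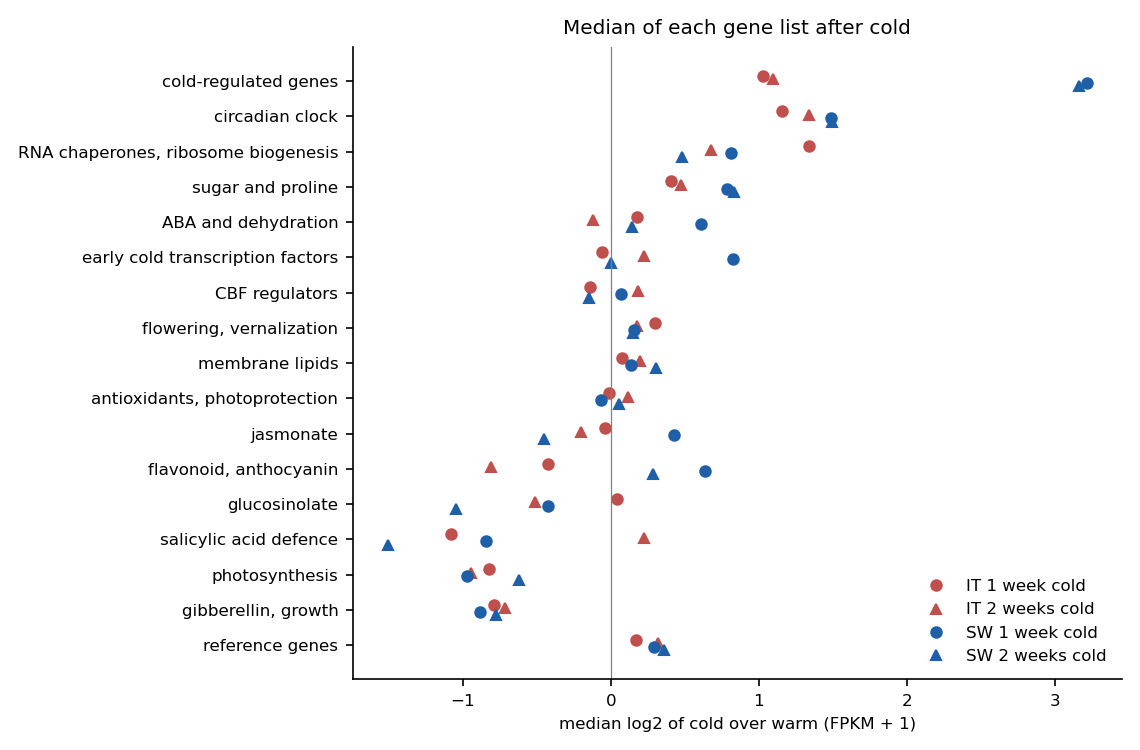
Median log2 ratio of cold over warm (FPKM + 1) for 16 of the gene lists and the reference genes, in IT (red) and SW (blue) after 1 week (circles) and 2 weeks (triangles), where each point is the median over the measured members of a list. The cold-regulated list sits at 1.03 and 1.095 in IT and at 3.22 and 3.17 in SW.

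The cold responses of both ecotypes were then set side by side; they share no warm group. After 1 week 818 genes were at least 2-fold higher in both, against 148.8 expected for independent lists, and 728 were at least 2-fold lower in both, against 93.3. KIN1, COR15A, LTI30, ELF4 and FKF1 were among those higher in both, and EXPA8, RBCS3B and WRKY70 among those lower in both. Across 19218 genes the log2 ratios of IT and SW had a Pearson r of 0.745 and a Spearman rho of 0.744; genes are not independent replicates. After 2 weeks 679 genes were higher in both (87.3 expected) and 700 lower in both (91.8 expected), with r of 0.724 and rho of 0.731 over 19223 genes. Reference-gene scaling changed the shared counts to 379 higher and 1370 lower at 1 week and to 220 higher and 2161 lower at 2 weeks, and a pseudocount of 0.1 gave 1082 lower in both at 2 weeks.

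**Figure D3:**
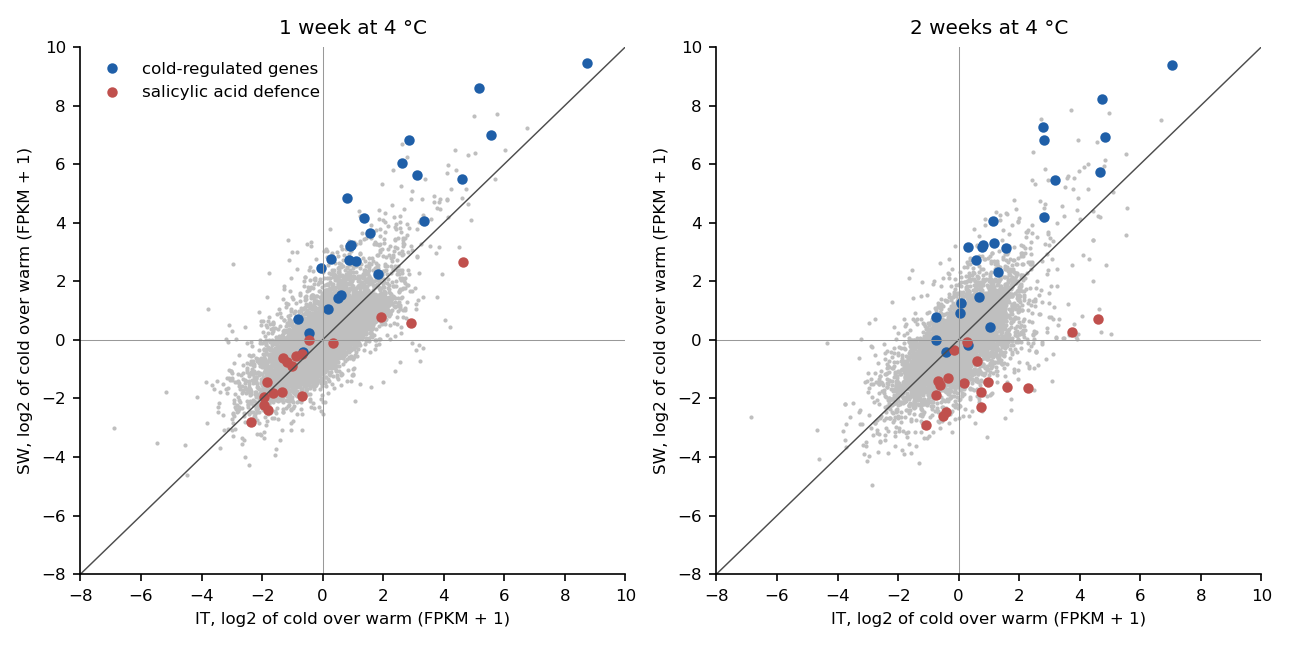
Log2 ratio of cold over warm (FPKM + 1) in IT (x axis) and SW (y axis) after 1 week (left) and 2 weeks (right), 1 point per gene with a ratio in both ecotypes (19218 and 19223 genes), with cold-regulated genes in blue, salicylic acid defence genes in red and the line of equal ratios. Most cold-regulated genes sit above the line, and after 2 weeks PR1, PR2 and PR5 sit far below it.

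Defence transcripts stood higher in the Italian plants after 2 weeks of cold than after 1 week. In the salicylic acid list 12 of 18 genes were at least 2-fold higher at 2 weeks than at 1 week and 0 were lower (median 1.28, above all 10000 matched random lists, and 0.91 under reference-gene scaling). The salicylic acid conjugation gene PBS3 was at 58.5 FPKM against 13.4, the transporter gene EDS5 at 32.4 against 8.34 and PR1 at 11644 against 3336, while PR5 hardly differed (6916 and 7128). Among the 6 largest ratios were those of 3 defensin paralogs that may share reads, with PDF1.2a at 439 FPKM against 39.7, PDF1.2c at 371 against 33.8 and PDF1.3 at 71.6 against 5.92. Defensin-like genes as a family, chosen after the values were seen, did not stand out, with 4 of 16 higher, 1 lower and a median at percentile 94.2 of the matched random lists. AT1G33950, AIG1 and DIN2 had log2 ratios of 3.50, 3.42 and 3.15.

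Glucosinolate genes went the other way in IT, with 8 of 27 at least 2-fold lower and 1 higher (median -0.82, below all 10000 matched random lists), MAM1 being at 259 FPKM against 707, SOT17 at 27.4 against 75.4 and MYB51 at 18.9 against 5.73. RNA chaperone and ribosome assembly genes had 2 of 18 lower and 0 higher (median -0.77), including FIB2 (-1.35) and NOP56 (-1.20). Early cold transcription factors had 3 of 15 higher and 1 lower (median 0.58, and 0.27 under reference-gene scaling), among them WRKY33 (1.38) and ERF11 (1.18), against CRF2 at -1.37. All 5 measured flower markers were at least 2-fold higher (median 1.21), and of the 4 senescence markers SAG29 (2.15) and SAG12 (1.44) were higher. The cold genes differed little, with log2 ratios of 0.34 for CBF1, -0.18 for CBF2, 0.16 for CBF3, -0.73 for COR15A, -0.06 for RD29A, 0.09 for KIN2, 0.22 for GOLS3 and -0.66 for FLC; KIN1 was lower at -1.70. Clock genes were all within 2-fold. The 6 largest ratios on the lower side were those of AT1G53543 (-3.40), the lipid transfer protein gene LTP3 (-2.27) and 4 small nucleolar RNA genes (AT4G02555, AT1G75166, AT1G12015 and AT3G24612). FPKM values of this short class may be unstable, which was not tested. The class as a whole made up 3.84% of the FPKM sum in IT at 1 week and 1.68% at 2 weeks. Over all genes 352 were at least 2-fold higher and 287 lower (55.1% higher), against 158 and 1165 (11.9%) under reference-gene scaling, which shifted the median by -0.34, and 651 and 482 with a pseudocount of 0.1.

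Jasmonate genes and early cold transcription factors were lower in the Swedish plants after 2 weeks of cold than after 1 week. Among single genes with the largest ratios, the starvation-linked gene DIN11 was at 1.96 FPKM against 106, the defensin gene LCR67 at 0.126 against 36.5, the late embryogenesis abundant gene LEA7 at 0.263 against 40.1 and the peroxidase gene Prx37 at 0.674 against 40.3. SIS (-4.26) and UGT74E2 (-4.12) followed. Early cold transcription factors had 6 of 15 at least 2-fold lower and 0 higher (median -0.56), including ZAT10 (-1.68), WRKY33 (-1.18) and ZAT12 (-1.15), with RAV1 at -0.49. Jasmonate genes had 4 of 11 lower and 0 higher (median -0.77), including JAZ10 (-1.45), VSP1 (-1.41) and JAZ1 (-1.32), with LOX2 at -0.83. Glucosinolate genes had 4 of 27 lower (median -0.62), such as MYB122 (-1.87) and SOT17 (-1.22), and the salicylic acid list 4 of 18 lower (median -0.21, at percentile 0.06 of the matched random lists), with PR2 at 105 FPKM against 491, PR5 at 322 against 1240.3 and FMO1 at -1.48 on the log2 scale. RAB18 was at 11.0 against 71.5.

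Cold-regulated genes mostly held their level in SW between the time points, with 22 of 24 within 2-fold and LEA7 and LEA4-5 (-2.75) lower. The log2 ratios were 0.76 for CBF1, 0.05 for CBF2, 0.18 for CBF3, -0.05 for COR15A, 0.44 for RD29A, -0.17 for KIN2, 0.79 for GOLS3 and -0.75 for FLC. AGL19, which promotes flowering after cold, was at 13.0 FPKM against 4.01. The 6 largest ratios on the higher side were those of the microRNA precursor MIR164b, the non-coding RNA gene AT1G15405, the small nucleolar RNA gene SNOR105, RL3 (1.87), AT4G15660 (1.87) and AT7SL-1 (1.84). In all 79 genes were at least 2-fold higher and 557 at least 2-fold lower of 19358 (12.4% higher), against 220 and 925 with a pseudocount of 0.1. Each of these ratios uses the 1 combined value of SW at 1 week. That value also enters SW at 1 week against SW warm and against IT, and the interaction at 1 week. The design cannot part time in the cold from another event in the SW plants at 1 week.

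The ecotypes were first compared in the warm, where the anthocyanin genes were lower in SW. UGT79B1 was at 1.01 FPKM in SW against 15.6 in IT, GSTF12 at 7.14 against 65.2 and UGT75C1 at 3.71 against 30.2, with CHS within 2-fold (137 against 226). In the flavonoid list 9 of 23 genes were at least 2-fold lower in SW and 0 higher (median -0.75, below all 10000 matched random lists). Several cold genes were lower in SW before any cold, with KIN2 at 97.3 FPKM against 417, RD29A at 8.97 against 25.7, ERD7 at 19.2 against 52.5 and CBF3 at 1.09 against 3.65. The log2 ratios of CBF1, CBF2, COR15A and GOLS3 were -0.11, -0.19, 0.02 and -0.06. Of 24 cold-regulated genes 4 were at least 2-fold lower in SW and 0 higher (median -0.21, below all 10000 matched random lists).

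FLC and its target SOC1 differed between the ecotypes in the warm, while the flowering list as a whole had 10 of 16 genes within 2-fold and a median of -0.08, at percentile 13.6 of the matched random lists. FLC was at 167 FPKM in SW against 63.2 in IT, and SOC1 at 4.07 against 40.0. MAF4 (0.166 against 4.31) and MAF5 (0.176 against 3.99) were lower in SW, 4 genes of the list being lower and 2 higher in all. Clock genes had 3 of 21 lower in SW (median -0.29), PRR5 (-2.47), FKF1 (-1.79) and ELF4 (-1.07), with CCA1 at 0.53. The salicylic acid list had a median of -0.52, below all 10000 matched random lists, with SARD1 at -1.25, PBS3 at -1.05, ALD1 at 1.105 and PR1 at -0.27. In the jasmonate list PDF1.2b (2.32) and VSP1 (1.45) were higher in SW and VSP2 (-1.72) lower, and in the glucosinolate list FMOGSOX3 (1.35) and MAM3 (1.08) were higher and MAM1 (-1.54) lower. The proline synthesis gene P5CS1 was at 236 against 108 FPKM. The membrane lipid list had 14 of 14 genes within 2-fold.

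The largest ecotype ratios in the warm belonged mostly to genes without a place in the lists. AT2G25510 was at 4895 FPKM in SW against 16.2, AT3G62530 at 1154 against 3.76, AT3G62460 at 293 against 0.642, AT1G24388 at 111 against 0.149 and QQS, a starch-linked gene, at 97.8 against 0.24. In IT the RNA gene AT4G38932 was at 457 FPKM against 0.908 in SW, the wall-associated kinase gene WAK2 at 110.3 against 0.535, AT2G44240 at 97.8 against 0.252 and the thionin gene THI2.2 at 92.5 against 0.471. AT5G33251 (6.27), SADHU5-1 (-7.02) and AT3G45050 (-5.60) completed them. Over all 3 conditions 247 genes were at least 2-fold higher in SW each time and 305 at least 2-fold higher in IT each time, of 19168 compared (189 to 410 and 262 to 512 under the alternatives). Sequence differences from the reference can lower the mapped reads of an ecotype, and this was not measured here. In the warm 518 genes were at least 2-fold higher in SW and 816 at least 2-fold lower, against 791 and 1269 with a pseudocount of 0.1.

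After 1 week of cold the cold-regulated genes were higher in SW than in IT. GOLS3 was at 205 FPKM in SW against 19.1 in IT, COR47 at 1490.4 against 242, RD29A at 1126 against 193 and COR15A at 13809.5 against 5067, while KIN2 lay within 2-fold (4888 against 3591). Of 24 such genes 14 were at least 2-fold higher in SW and 0 lower (median 1.27, above all 10000 matched random lists, and 0.78 under reference-gene scaling). The CBF genes differed by less than 2-fold, CBF1 at 0.32, CBF2 at 0.48 and CBF3 at 0.61 on the log2 scale. FLC was at 176 FPKM against 48.2, MAF3 at 82.0 against 14.2 and MAF4 at 0.101 against 3.55.

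Sugar and jasmonate genes were higher in SW and salicylic acid genes lower. The sugar and proline list had 5 of 20 at least 2-fold higher in SW and 0 lower (median 0.61, and 0.14 under reference-gene scaling), with SUS1 at 285 FPKM against 72.2 and GOLS1 at 70.7 against 31.3. The jasmonate list had 5 of 11 higher and 1 lower (median 0.95, and 0.45 under that scaling), with PDF1.2a at 2.73, PDF1.2b at 2.55, VSP2 at -1.69 and AOC2 at 0.95. The abscisic acid list had 2 of 15 higher in SW and 1 lower, with a median of 0.39 that turned to -0.07 under reference-gene scaling; RAB18 was at 2.31, ADH1 at 1.46 and CYP707A3 at -1.28. The salicylic acid list had 6 of 18 lower in SW and 0 higher (median -0.57, and -0.98 under reference-gene scaling). PR2 was at 491 FPKM against 3079, PR5 at 1240.3 against 7128 and PR1 at 1246 against 3336. EXPA1 was at 13.5 against 58.5. All 21 clock genes lay within 2-fold between the ecotypes, as did 18 of 18 RNA chaperone and ribosome assembly genes. AT1G69140 (7.51) joined AT2G25510 (8.44), AT1G24388 (7.64), AT3G62530 (7.44), AT3G62460 (7.27) and AT5G33251 (7.17) at the top in SW. SADHU5-1 (-7.63), AT2G15128 (-7.56), AT4G38932 (-7.11), AT3G24516 (-6.64), THI2.2 (-6.24) and AT2G14285 (-5.63) had the largest ratios in favour of IT. In all 883 genes were at least 2-fold higher in SW and 763 lower (53.6% higher). Reference-gene scaling shifted the median of all genes by -0.43 and gave 477 and 1956 (19.6%), and a pseudocount of 0.1 gave 1328 and 1238.

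After 2 weeks the ecotypes differed most in salicylic acid defence. PR5 was at 322 FPKM in SW against 6916 in IT, PR2 at 105 against 2001, PR1 at 870.0 against 11644 and EDS1 at 24.4 against 46.1. Of 18 genes of the list 15 were at least 2-fold lower in SW and 0 higher (median -2.34, below all 10000 matched random lists). The senescence marker SAG13 was at 17.7 FPKM against 291, and 4 of 5 flower markers were lower in SW (median -1.29), such as SEP3 at 0.109 against 2.60. Early cold transcription factors had 4 of 15 lower in SW (median -0.46), including WRKY33 (-1.93), ZAT10 (-1.77) and ZAT12 (-1.46). Glucosinolate genes went both ways, FMOGSOX3 (1.90) and AOP2 (1.76) being higher in SW and CYP79B2 (-1.70) lower.

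**Figure D4:**
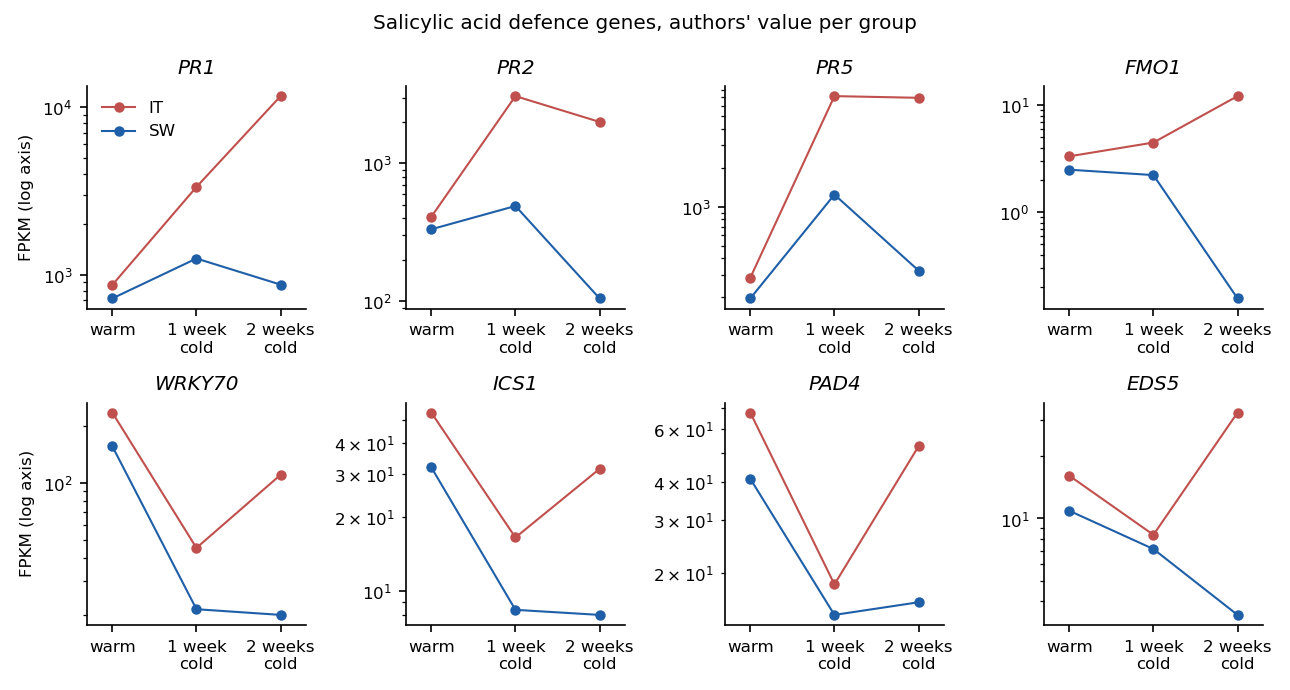
FPKM on a log axis, 1 combined value per group without error bars, of 8 salicylic acid defence genes (PR1, PR2, PR5, FMO1, WRKY70, ICS1, PAD4 and EDS5) in IT (red) and SW (blue) in the warm and after 1 and 2 weeks at 4 °C. EDS5 stood at 32.4 FPKM in IT and 3.43 in SW after 2 weeks.

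Cold-regulated and sugar genes stayed higher in SW at 2 weeks. The cold-regulated list had 15 of 24 genes at least 2-fold higher and 0 lower (median 1.28, above all 10000 matched random lists), with GOLS3 at 354 FPKM against 22.5, RD29A at 1532 against 185, COR47 at 1376 against 209.8, COR15A at 13319 against 3062 and KIN2 at 4343 against 3824. CBF1, CBF2 and CBF3 had log2 ratios of 0.74, 0.70 and 0.63. The sugar and proline list had 8 of 20 higher in SW and 1 lower (median 0.77), including SUS1 (1.76) and the starch breakdown gene DPE2 (1.35). All 22 measured photosynthesis genes lay within 2-fold, with a median of 0.62, at percentile 99.99 of the matched random lists. In the flavonoid list 5 of 23 genes were higher and 3 lower in SW (median -0.05, at percentile 15.3 of the matched random lists). MYB111 (1.94), the anthocyanin regulator PAP1 (AT1G56650, 1.81) and CHS (1.72) were among the higher genes, and the lower genes, chosen after their values were seen, were UGT75C1 (-1.67), UGT79B1 (-1.29) and SCPL10 (-1.09). FLC was at 105 FPKM against 30.0 and MAF3 at 78.6 against 12.4. The largest ratios were those of AT2G25510 (8.20), AT3G62530 (8.004), AT1G69140 (7.64), AT5G33251 (7.56), AT3G62460 (7.37) and AT1G24388 (7.25) in SW. In IT they were those of AT2G15128 (-8.23), SADHU5-1 (-8.15), AT4G38932 (-7.39), AT3G24516 (-6.80), THI2.2 (-6.32) and AT5G44570 (-5.84). In all 758 genes were at least 2-fold higher in SW and 1390 lower, and reference-gene scaling shifted the median by -0.13.

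The interaction of ecotype and cold, the log2 cold response of SW less that of IT, asks whether the responses differ in size. At 1 week it was 3.96 for RD29A, 4.03 for LEA7, 3.44 for LTI30, 3.41 for GOLS3, 2.53 for KIN2 and 1.43 for COR15A. For CBF3 it was 1.76, mostly through its lower warm level in SW, with SW against IT at -1.16 in the warm and 0.61 at 1 week. For CBF1 and CBF2 it was 0.42 and 0.67. Warm values of CBF1 and CBF2 lie below 1 FPKM, and with a pseudocount of 0.1 the values were 1.11 for CBF1, 0.96 for CBF2 and 2.28 for CBF3. In the cold-regulated list 15 of 24 genes had an interaction of at least 1 and 0 of -1 or less (median 1.71, above all 10000 matched random lists), COR15B lying below 1 at 0.88. The flavonoid list had 12 of 23 at 1 or more and 1 at -1 or less (median 1.11), with FLS1 at 2.45, PAP1 at 2.43, GSTF12 at 1.95 and MYBL2 at 0.45. For the list this came mostly from lower warm levels in SW, as the median of SW against IT was -0.75 in the warm and 0.08 at 1 week (-0.40 under reference-gene scaling). FLS1 (1.23) and PAP1 (1.67) were also higher in SW at 1 week, while GSTF12 (-1.08) was still lower. The KIN2 value also came mostly from the warm level, with SW against IT at -2.09 in the warm and 0.44 at 1 week. Abscisic acid genes (6 of 15, median 0.83), jasmonate genes (5 of 11, median 0.86), sugar and proline genes (5 of 20, median 0.74) and clock genes (4 of 21, median 0.51) also had members at 1 or more, such as RAB18 (2.37), PDF1.2a (1.69), SUS1 (1.65) and PRR5 (2.57). For the clock much of this lay in the warm, with a median of SW against IT of -0.29 there and 0.18 at 1 week. All 21 clock genes were within 2-fold between the ecotypes at 1 week, and PRR5 was lower in SW in the warm. RNA chaperone and ribosome assembly genes were on the other side (3 of 18 at -1 or less, median -0.60), with FIB2 at -1.69 and NOP56 at -1.28 but GRP7 at 1.25. FLC was at 0.46. The largest values were those of DIN2 (5.54), AT4G01390 (4.85), UGT74E2 (4.57) and AT1G15010 (4.04), and the lowest those of the small nucleolar RNA gene SNOR95 (-3.95), AT3G49340 (-3.77), WRKY30 (-3.59) and AT3G54830 (-3.45). Over all genes 940 were at 1 or more and 467 at -1 or less (66.8% on the higher side). Reference-gene scaling shifted the median by -0.38 and turned that majority, to 514 and 2035 (20.2%), and a pseudocount of 0.1 gave 867 at -1 or less. The same scaling by reference genes lowered the list medians to 1.29 for the cold-regulated, 0.67 for the flavonoid, 0.40 for the abscisic acid, 0.44 for the jasmonate, 0.30 for the sugar and 0.09 for the clock genes. For the RNA chaperone and ribosome assembly genes it gave -1.05.

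At 2 weeks the interaction separated defence from cold genes. In the salicylic acid list 13 of 18 genes were at -1 or less and 0 at 1 or more (median -1.92, below all 10000 matched random lists), with PR2 at -3.94, PR5 at -3.89, PR1 at -3.47 and EDS1 at -0.73. In the cold-regulated list 18 of 24 were at 1 or more and 0 at -1 or less (median 1.85, above all 10000 matched random lists), with RD29A at 4.46, GOLS3 at 3.98, LTI30 at 3.49, KIN2 at 2.27 and COR15A at 2.102. CBF1, CBF2, CBF3 and FLC were at 0.84, 0.89, 1.78 and 0.38. With a pseudocount of 0.1 CBF1 was at 1.59, CBF2 at 1.19 and CBF3 at 2.302. The CBF3 and KIN2 values again came mostly from the warm level, with SW against IT at 0.63 and 0.18 at 2 weeks. The flavonoid list had 14 of 23 at 1 or more (median 1.14), with FLS1 at 2.66, PAP1 at 2.56 and CHS at 2.44. The list again differed less in the cold than in the warm, with a median of -0.05 for SW against IT at 2 weeks, although these 3 genes were higher in SW then. PDF1.2c (-4.83), WRKY30 (-4.51), the transporter gene ABCG40 (-4.45) and TAT3 (-4.23) had the lowest values. CIPK25 (4.79), RD29A, AT4G01390 (4.25) and NUDT24 (4.24) had the highest. In all 590 genes were at 1 or more and 810 at -1 or less, the second being 1242 with a pseudocount of 0.1.

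Few root and seed markers reached 1 FPKM. Of 8 root markers 2 were measured, and of these WOX5 was at 4.95 FPKM in SW after 2 weeks against 1.03 in SW warm and 1.68 in IT after 2 weeks. Of 5 seed markers 4 stayed below 1 FPKM in all 6 groups, and CRU3 was listed at 0 in all 6, which gives no level, as abundant genes were also listed at 0. The epidermis and vein markers lay within 2-fold in all 4 cold to warm comparisons. SUC2 of the phloem was at 84.3 FPKM in IT warm and 89.4 in SW after 2 weeks, groups that differ in both ecotype and condition. The floral markers named for IT at 2 weeks, all below 3 FPKM, stood beside the higher FT and SOC1 values of that group.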

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

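Every weighing test in this part was chosen after its result was seen, and the counts that open it come from a comparison fixed in advance. After 1 week of cold 6 genes were at least 2-fold higher in IT and at least 2-fold lower in SW, and 18 were lower in IT and higher in SW. After 2 weeks the numbers were 24 and 7. These counts depend on the pseudocount: in the same order they were 15, 44, 76 and 15 with 0.1 and 12, 34, 56 and 11 with 0.25. Of the same counts, 18 went to 11 under reference-gene scaling and 6 went to 11 with genes listed at 0 kept. They were picked out because the ecotypes went opposite ways, and the difference between them was not tested, since each group has 1 value. The genes named next were chosen after their values were seen. At 1 week the legume lectin gene AT5G03350 had log2 ratios of 1.60 in IT and -1.62 in SW, but its level stayed higher in SW. It was at 13.7 FPKM in IT warm and 43.7 in IT at 1 week, against 487.7 and 157.8 in SW. DIN2 had log2 ratios of -2.95 in IT and 2.59 in SW, and the nitrilase gene NIT2 of -1.001 and 2.99. At 2 weeks WRKY30 had 3.09 in IT and -1.41 in SW, the chitinase gene CHI 1.72 and -2.38, PR2 2.28 and -1.66, FMO1 1.60 and -1.60 and SAG13 1.08 and -1.84, while the zinc finger gene OZF1 had -1.20 and 1.97.

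Salicylic acid defence genes were lower in SW than in IT after 2 weeks of cold. A loss of Swedish reads on the Columbia reference would hold in the warm too, but the list was also lower after the warm difference was taken off (median -1.92, quartiles -2.90 to -0.99, 18 of 18 genes below 0), which argues against it as the whole cause. Under the 3 other scalings the median closest to 0 was -2.33. They shifted the median of all genes in this comparison by only -0.13 to 0.04, so they could not have removed the gap. They show no more than that the gap is larger than the differences between these scalings. An event other than cold in the IT plants, such as an infection or the onset of flowering, stays open as a part of the cause. The list was higher in IT at 2 weeks than at 1 week (median 1.28, 12 of 18 genes at 2-fold or more), against a median of -0.21 in SW. The design cannot part this from time in the cold. PR2 was lower in IT at 2 weeks than at 1 week (2001 against 3079 FPKM). Against the warm the list median at 2 weeks was 0.22 in IT and -1.51 in SW. An event in IT alone would leave the lower SW values unaccounted for. A difference between the ecotypes in how defence answers to cold stays open as well, untested.

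Cold-regulated genes were higher in SW than in IT in the cold. A loss of Italian reads is argued against as the whole cause by the difference of the cold responses at 1 week (median 1.71, quartiles 0.89 to 2.52, 24 of 24 genes above 0). A weaker IT response in all cold-induced genes is argued against by 1573 other genes with a mean log2 response over both ecotypes of 1 or more, whose SW response less the IT response had a median of -0.25 (quartiles -0.73 to 0.49), against 2.29 (quartiles 1.18 to 2.67) for the 19 cold-regulated genes chosen by the same mean. A lower CBF transcript level in IT could contribute, as CBF1, CBF2 and CBF3 had a median of 0.48 against 1.27 for the cold-regulated list at 1 week, but 3 genes at a single hour decide nothing. A change in CBF protein or in its targets stays open, untested.

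Some abundant photosynthesis genes were listed at exactly 0 in whole groups: LHCA4 and RCA in both warm groups and LHB1B2 in IT warm, against at least 2623 FPKM in the IT cold groups, a level that argues against a gene missing from the ecotype. Failed estimates at crowded loci could give such zeros. Of 3 genes that overlap LHCA4, LHB1B2 or RCA, 2 were at 0 in exactly the same groups: ATSMC2 over LHCA4 and RWA3 over LHB1B2, where 0.0611% and 0.153% of the 19639 kept genes were at 0 in those groups. The gene over RCA, AT2G39725, was not, and every one of the 3 was needed, so this stays open. Among all expressed genes that overlap an abundant gene listed at 0, 12.5% shared its zeros, against 6.76% of near genes that do not overlap. That 12.5% is 2 of 16 pairs, the same 2, and adds no separate evidence. Absence from warm plants of both ecotypes is argued against for LHB1B2 by its 8039.9 FPKM in SW warm. For LHCA4 and RCA the listed 0 gives no level and so does not show absence from warm plants. LHCB1.1, LHCB1.2, LHCB1.3 and RBCS1A were likewise listed at 0, in all 6 groups. The relatives LHCA1, LHCA2 and LHCA3 stood at 3959 FPKM or more in both warm groups, which alone does not settle LHCA4 and RCA. Because of these zeros, genes listed at 0 were given no ratio.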

How the results depend on the processing

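Of the 9 alternatives, 2 (genes listed at 0 kept, and protein-coding genes only) were chosen after the data were seen. Of 26 main counts none went beyond 1.5 times the reported value, up or down, without a filter, with a filter of 5 FPKM, under upper-quartile scaling or quantile normalization, or under the 2 added alternatives. The majority of higher over lower genes nevertheless turned in cold against warm under reference-gene and upper-quartile scaling in IT at 1 and 2 weeks and SW at 1 week, and under quantile normalization in the last 2. With a pseudocount of 0.1, higher and lower counts went to 651 and 482 for IT 2 weeks against 1 week, 220 and 925 for SW 2 weeks against 1 week, 791 and 1269 for SW against IT in the warm and 1328 and 1238 at 1 week. Lower counts went to 867 and 1242 for the interactions at 1 and 2 weeks, and genes lower in both ecotypes at 2 weeks to 1082. With a pseudocount of 0.25 they were 563 and 431 for IT 2 weeks against 1 week, 175 higher for SW 2 weeks against 1 week and 750 lower for the interaction at 1 week. Of 823 gene ratios 175 moved by more than 0.5 with a pseudocount of 0.1 and 148 with 0.25, as did 158 under reference-gene scaling and 25 under quantile normalization. Of 216 list medians 26 moved that far under reference-gene scaling, all downward and all in cold against warm (IT at 2 weeks and SW at both times), 9 and 7 with the smaller pseudocounts and 2 under quantile normalization. A smaller pseudocount widens ratios of low values by construction. Reference-gene scaling (factors 0.783 to 1.25) gave 547 and 3145 for IT 2 weeks, 684 and 3271 for SW 1 week, 470 and 3828 for SW 2 weeks, 158 and 1165 for IT 2 weeks against 1 week, 477 and 1956 for SW against IT at 1 week and 514 and 2035 for the interaction at 1 week. Genes higher and lower in both ecotypes then numbered 379 and 1370 at 1 week and 220 and 2161 at 2 weeks. Each group is shifted by 1 factor there, taken from the median level of the reference genes and not from their ratios gene by gene. It overshot these genes themselves in IT at 2 weeks and in SW at both times. Their own median cold ratio there went from 0.32 to -0.18, 0.29 to -0.23 and 0.36 to -0.25, in that order. For IT at 1 week it went from 0.17 to 0.08. Part of each larger downward move under this scaling is therefore overshoot. In cold against warm the 12 reference genes lay at percentiles 36.2 to 71.5 of random lists matched on expression, and so did not stand out from genes of like abundance; for IT at 2 weeks against 1 week they lay at percentile 97.7. Why such genes differ from the rest was not tested. No gene ratio or list median of at least 1 in size changed sign in any alternative. Smaller list medians changed sign in 56 cases under reference-gene scaling (up to 0.48 in size before it), 24 under quantile normalization (up to 0.24) and 8 under upper-quartile scaling (up to 0.0766). The cause was not tested. No paired analysis was possible because there is 1 value per group. Without values per library, eBayes without trend, arrayWeights, a replicate block, the libraries of the compared groups alone, leave-one-out, camera, fry and an estimated inter-gene correlation were not run; the added fold limit equals the call used. The unknown depth limits what can be said of genes near 1 FPKM.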

Other observations

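The gene families in this part were chosen after the main results were seen, by words in the gene descriptions. Of 16 families tried 5 are given, picked for their values. Of 176 medians over all families and comparisons 15 lay above and 37 below all 10000 matched random lists, and each median given here is among those. Ribosomal protein genes were higher in the cold, most of all in IT after 1 week, where 208 of 313 were at least 2-fold higher and 2 lower (median log2 ratio 1.36). In IT after 2 weeks 115 were higher and 2 lower (median 0.81), and in SW 72 after 1 week and 72 after 2 weeks, with 1 lower each time (medians 0.73 and 0.73). Genes of SAUR-like proteins, a class of auxin-responsive growth genes, were lower, with 19 of 52 at least 2-fold lower in IT and 31 of 51 in SW after 1 week (medians -0.83 and -1.11; 3 and 2 genes higher), and 24 and 27 after 2 weeks (medians -0.86 and -1.14; 3 and 2 higher). In SW against IT after 2 weeks 22 of 42 WRKY genes (median -1.02) and 14 of 28 genes of cysteine-rich receptor-like kinases (median -1.13) were at least 2-fold lower and 0 higher, beside the salicylic acid defence genes. Glutathione S-transferase genes in SW had 19 of 49 at least 2-fold higher and 1 lower after 1 week of cold (median 0.61). At 2 weeks against 1 week 18 were at least 2-fold lower and 0 higher (median -0.58). Both ratios use the same SW 1 week value, so high values in that group alone would give both results. None of the medians given here changed sign under upper-quartile, quantile or reference-gene scaling. An unchanged sign does not mean an unchanged size. Reference-gene scaling shifted the median of all genes in cold against warm SW plants by -0.46 at 1 week and -0.52 at 2 weeks. The ribosomal protein and glutathione S-transferase medians above 0 in those comparisons were thus smaller under it.

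Some genes were seen almost only in 1 ecotype. At least 5 FPKM in all 3 IT groups and less than 0.5 FPKM in all 3 SW groups were found for 45 genes (34 protein coding), and the reverse for 38 (29 protein coding). A listed 0 was counted as below 0.5 FPKM here, although it gives no level. Sequence differences from the reference, which can lower the mapped reads of an ecotype, were not measured. LHCB1.1, LHCB1.2, LHCB1.3 and RBCS1A, genes of abundant photosynthesis proteins, were listed at 0 in all 6 groups. The CBF relatives CBF4, DDF1 and DDF2 stayed below 1 FPKM in all 6 groups.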
